A study of Oryza sativa with 12 samples.

How the data were processed

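Small RNA libraries of the rice near-isogenic lines XN0437S and XN0437T were prepared with a TruSeq Small RNA kit and sequenced on a HiSeq 2500, per the labels' protocols. Per the same protocols, the authors' cleaning of the reads with ACGT101-miR removed adapter dimers, junk, low-complexity reads, repeats and reads of ribosomal, transfer, small nuclear and small nucleolar RNA. The mapping settings, the miRBase release and the genome build are not given in the sources used here. Each of the 12 libraries was put in its group from its title, and replicate numbers were taken from the same label.

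One deposited table held all libraries. Its columns of raw values are expected counts, judged from the values in the deposited file: the reads of a mature sequence were divided evenly over the loci it fits, so that 65.5% of positive values were whole before and 85.2% after the values of 1 sequence were summed (tolerance 1e-06). Its normalised columns hold a signal that the authors obtained by multiplying the raw values of each library by 1 factor, judged from the deposited values; the factors ran from 0.589 to 1.472 and how they were derived is not given in the sources used here. The table gives for each hairpin a chromosome, start and end, which are printed as in the table. Of 8325 positive values after summing, 1037 were exactly 5 and 545 were lower, of which 61.5% were divided reads, so the table lists almost no read found in fewer than 5 copies. Its values are thus cut off at the low end, a 0 can stand for up to 4 copies, and no upper limit is attached to a 0. Totals per library ran from 333406 to 866773 reads, the lowest in sensitive control 1 and the highest in tolerant control 2. These are totals of the listed microRNA reads, so shares are shares of listed reads and not of whole libraries. Spread between libraries was far above counting noise in every pair of replicates (chi-square over degrees of freedom from 2.53 to 43.5), and no pair looked like 1 library deposited more than once.

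The table had 1642 entries with values and 1325 distinct mature sequences; 30 lines were emptied before use and are not analysed here. Entries of 1 sequence were summed (317 merged into others), rounded to whole numbers and tested. The design written before the data were examined had assumed whole reads repeated at each locus, with 1 entry kept; since the values proved to be divided reads, summing was used, a choice made before any test, and keeping 1 entry was run as an alternative. The count model was edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr (minimum count 10, minimum total 15, minimum proportion 0.7), estimateDisp and the quasi-likelihood F test, with 1 coefficient per group and all 12 libraries in 1 model (common dispersion 0.0804, prior df 4.86). Benjamini-Hochberg adjustment at 0.05 was applied over the 471 sequences of each contrast. SE values are the log2 change divided by the square root of F. Family totals sum all sequences with 1 miRBase family number, including those named for other species, and were adjusted over all 160 families and over the 47 families of the lists; p-values printed for list families are the latter, those for other families the former. CPM values use the TMM-scaled library sizes.

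The lists were fixed before the data were examined, from knowledge of plant microRNA families: auxin signalling (miR160, 167, 390, 393), developmental transcription factors (miR156, 159, 164, 166, 169, 171, 172, 319, 396, 444, 529), copper and redox (miR397, 398, 408, 528), nutrient (miR395, 399, 827), DCL1 and AGO1 (miR162, 168), Arabidopsis heat responses (miR156, 160, 398), rice grain size or filling (miR156, 396, 397, 408, 1432), monocot or rice families, reproductive triggers as markers of other tissue (miR2118, the only family of that list among the sequences tested), sequences of 24 bases, sequences of 21 bases, and the authors' candidates without a miRBase name. Several lists share families. They were tested with camera of limma 3.58.1 (correlation 0.01, log2 CPM with prior count 2), again with an estimated correlation, and with fry (directional test unless the mixed one is named), adjusted over all lists and contrasts. Shares by length were compared with two-sided exact permutation tests in scipy 1.17.1, and tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

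Sequences named in the text followed a rule fixed in advance. Per contrast they had an adjusted p under 0.05, a mean of at least 10 CPM in a compared group and, except for the interaction, no overlap between the libraries compared. From these came the 8 largest changes in each direction with a family name, at most 1 per family and arm, and the 3 largest in each direction among candidates; 98, 79, 31, 41 and 17 sequences met the conditions. Every list family that passed over the list families and the 5 most abundant families were named too. List examples and non-passing families named beyond this rule were chosen after their values were seen. The steps were tested on simulated data drawn from the means and totals of the real libraries. Every simulated sequence had the common dispersion of 0.0804 and no floor of 5 copies, so the rates below hold for that simpler setting. For the sensitive-line HNT comparison, with 446 simulated sequences tested, 37.2% of 43 changed 2-fold and 97.1% of 34 changed 4-fold were recovered, 3.92% of calls were false, and the unchanged tolerant comparison gave 0 calls. At this depth many 2-fold changes would thus be missed.

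Alternatives fixed in advance were DESeq2's size factors, no scaling beyond the total, TMM without the 10 highest sequences, no filter or a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, limma on log2 of the normalised value plus 1 or 0.1, only the compared groups in the fit, the replicate number as a block, only sequences with a family name, sums per name without variant suffix, only families from rice names, and each library left out in turn. Added after seeing the data were 1 entry kept per sequence, the authors' factors in edgeR, a mean of at least 50 reads, camera with each library left out (correlation preset or estimated), and the removal of sequences with motifs of transfer RNA (22 like the 5' part, 26 like the 3' end) or of 18S ribosomal RNA (1). Other ribosomal RNA was not searched. No genome sequence was used, and a table of gene names of another assembly was not used here.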

Results

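Small RNA was sequenced from a pair of near-isogenic rice lines, the heat-sensitive XN0437S and the heat-tolerant XN0437T, grown at the filling stage under a control regime or under high night temperature (HNT). The 12 libraries formed 4 groups of 3: sensitive control, sensitive HNT, tolerant control and tolerant HNT. The protocol text of the labels speaks of 9 libraries while 12 are listed, and which number is right is not given in the sources used here. The labels name the tissue only as rice and do not say that the 3 libraries of a group came from separate plants, so the p-values measure the spread between these libraries, which may be technical. The table held 1325 distinct mature sequences, of which 743 carried a miRBase family name and 582 were candidates predicted by the authors without one. The table totals ran from 333406 to 866773 reads per library. Because the table listed almost no read found in fewer than 5 copies, these totals are not library depths and a value of 0 is not a measured absence. Of the 1325 sequences, 471 had enough reads to be tested, and all were tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05.

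The most abundant family was miR166, which targets class III HD-ZIP transcription factors, with a mean of 343352 CPM (counts scaled to library size) over all libraries. It was followed by miR444, which targets MADS-box factors in monocots, at 132912 CPM, and by miR1425, which targets pentatricopeptide repeat genes in rice, at 129955 CPM. The auxin response factor regulator miR167 followed at 65034 CPM and the GAMYB regulator miR159 at 34174 CPM. One sequence, osa-miR166a-3p, which the table places at 6 loci, took 25.9% to 35.8% of the table reads of each library. The table divides a read that fits several loci between them, and these parts were summed for each mature sequence before testing. Members of a family can still be near identical in sequence. Family totals are therefore given first, and single members should be read as uncertain where their sequences are near identical. Levels below are mean CPM ± SD over the 3 libraries of a group, and changes are log2 values ± SE.

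The first comparison asked which small RNAs changed under HNT in the heat-sensitive line. The largest fall among the families of the fixed lists was that of miR1861, a family described in rice, from 1052 ± 34.0 to 263 ± 22.4 CPM (log2 change -2.0 ± 0.14, n = 3 per group, adjusted p = 3.4e-07). miR528, a monocot family that targets ascorbate oxidase and other copper proteins, fell from 4988 ± 739 to 2013 ± 79.0 CPM (-1.31 ± 0.14, adjusted p = 1.1e-05). miR393, which targets the TIR1/AFB auxin receptors, fell from 950 ± 29.3 to 509 ± 46.3 CPM (-0.90 ± 0.14, adjusted p = 0.00023). The miR393 sequences tested singly were osa-miR393a and osa-miR393b-3p. The second is named for the 3p arm, and whether it acts on the receptors was not checked. In the other direction miR531 rose from 258 ± 84.9 to 849 ± 68.4 CPM (1.71 ± 0.23, adjusted p = 0.00012). miR390, which triggers trans-acting siRNAs against auxin response factors, rose from 1187 ± 137 to 2152 ± 137 CPM (0.86 ± 0.17, adjusted p = 0.0013). The abundant miR444 rose from 104082 ± 6118 to 161275 ± 3631 CPM (0.63 ± 0.10, adjusted p = 0.00023), while miR167 fell from 76692 ± 4233 to 54781 ± 2122 CPM (-0.49 ± 0.07, adjusted p = 0.00018).

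Other falls in the sensitive line were those of miR1873 (-1.54 ± 0.27), miR1432 (-0.94 ± 0.26), the phosphate-homeostasis family miR399 (-0.85 ± 0.17) and miR1850 (-0.85 ± 0.13). miR397, a family that targets laccases, rose by 0.58 ± 0.10, the plantacyanin regulator miR408 by 0.57 ± 0.15 and miR166 by 0.27 ± 0.08 (adjusted p = 0.02). The miR397 sequences tested were osa-MIR397b-p3, osa-MIR397a-p5 and osa-MIR397b-p5, all named as hairpin pieces. Whether they include the sequence that acts on laccases was not checked. With scaling by the total count alone the rise of miR166 was 0.12 ± 0.05 (adjusted p = 0.0489 over the list families and 0.0957 over all families). The abundant families miR1425 (0.05 ± 0.08, adjusted p = 0.62) and miR159 (0.27 ± 0.13, adjusted p = 0.10) did not pass. Of the 160 families tested, 10 rose and 21 fell; of the 47 list families, 7 rose and 12 fell when adjusted over the list alone, against 6 and 11 over all families. Among these 19 calls, those of miR168 (0.22 ± 0.08), miR529 (-0.49 ± 0.15), miR169 (-0.53 ± 0.16), miR3979 (-0.60 ± 0.22) and miR1870 (-1.70 ± 0.51) were each lost without at least 1 library. That of miR168 was lost without sensitive control 1, sensitive HNT 2 or 3 or tolerant HNT 2, and that of miR529 without sensitive control 3 or sensitive HNT 2 or 3. That of miR169 was lost without sensitive control 2 or 3 or sensitive HNT 2, that of miR1870 without sensitive control 2 or sensitive HNT 3, and that of miR3979 without any of 9 libraries. The highest adjusted p over those libraries and the other settings was 0.44 for miR168, 0.078 for miR529, 0.093 for miR169, 0.053 for miR1870 and 0.15 for miR3979.

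Counted by sequence, 50 rose and 48 fell in the sensitive line. The lists below were built by family number, so they hold opposite arms and other hairpin pieces beside the sequences that act on the targets. Of the 24 auxin-signalling sequences (miR160, miR167, miR390 and miR393), 6 rose, 4 fell and 14 did not pass, with osa-miR390-5p at 0.89 ± 0.17, osa-miR393b-3p at -0.86 ± 0.13 and osa-miR393a at -0.99 ± 0.25. Adjusted over the list alone 7 rose and 4 fell. Of the 94 sequences of families that target developmental transcription factors, 16 rose, 13 fell and 65 did not pass, the same counts as when adjusted over the list alone. The falls include aof-MIR166b-p5_2ss6GC17TG, which holds a stretch of 18S ribosomal RNA; osa-miR444f rose by 1.12 and osa-MIR169a-p3 fell by 1.57. Of the 11 copper and redox sequences 4 rose, 1 fell and 6 did not pass (4 and 3 adjusted over the list alone). Those that rose were led by osa-miR398a, a regulator of Cu/Zn superoxide dismutases, and osa-MIR397b-p3 (0.93 ± 0.12), and osa-miR528-5p fell (-1.30 ± 0.13). Of the 16 sequences of families with described roles in Arabidopsis heat responses (miR156, miR160 and miR398), 5 rose, 0 fell and 11 did not pass (6 and 0 adjusted over the list alone). Of the 24 sequences of families with described roles in rice grain size or filling, 7 rose, 1 fell and 16 did not pass (7 and 1 adjusted over the list alone). The fall was that of osa-miR1432-5p_R+1 (-0.92 ± 0.25), a regulator of an acyl-CoA thioesterase in grain filling. The 79 sequences of monocot or rice families split into 11 higher, 16 lower and 52 not passed (12 and 20 adjusted over the list alone). Of the 7 nutrient sequences edgeR called 1, osa-miR399d (-0.86 ± 0.16), with 4 at an unadjusted p under 0.05, and DESeq2 and limma each called 2. Of the 6 from families that target DCL1 or AGO1 edgeR called 1, osa-miR168a-3p_L-3 (0.65 ± 0.10), with 2 unadjusted, DESeq2 called 2 and limma 1. That sequence is the opposite arm of osa-miR168a-5p, the arm that targets AGO1, which did not pass (-0.12, adjusted p = 0.435). In edgeR each list had 1 call adjusted over the list alone too. Of the 5 sequences of miR2118, which triggers phased small RNAs in grass anthers, 0 passed in edgeR, over all sequences or adjusted over the list alone. For 1 the unadjusted p was under 0.05, and DESeq2 and limma called 0.

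Of the lists 0 passed limma's camera test in the sensitive line. The nutrient and monocot lists had an unadjusted p under 0.05, and the directional test of fry, which does not compare a list with other sequences, called the heat list upwards (adjusted p = 0.0493) and the monocot list downwards (adjusted p = 0.0211). Camera's adjusted p was 0.539 for auxin signalling, 0.854 for developmental factors, 0.653 for copper and redox, 0.111 for nutrient, 0.932 for DCL1 and AGO1, 0.329 for heat, 0.493 for grain, 0.2 for monocot families and 0.915 for miR2118. For the developmental list the median log2 change was 0.12 and the mean -0.24, and for the 21-base sequences 0.03 and -0.10.

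Hairpin positions are those of the table, whose genome build is not given in the sources used here. By single sequence, osa-miR398a (chromosome 10, 9216250 to 9216364) rose in the sensitive line from 13.2 ± 12 to 109 ± 7.35 CPM (2.88 ± 0.52, adjusted p = 0.00173). osa-miR531a_R-2 rose by 2.25 ± 0.23. gma-MIR5368-p5_2ss1TC21TC, listed at 0 in 2 of the 3 sensitive controls and at 61.5 ± 12.6 CPM under HNT, rose by an amount that the table cannot give. The miR5368 sequences were not compared with plastid or 25S ribosomal RNA. ath-miR8175_L-1, a sequence with the acceptor-stem end of a transfer RNA, rose by 1.72 ± 0.38, but not once its variants were summed (highest adjusted p 0.071). csi-miR160c-5p_R-1 (2.38 ± 0.73) and osa-miR444d.3_R-1 (2.27 ± 0.73) rose with calls that several left-out libraries ended, sensitive control 1 and 2 and sensitive HNT 2 and 3 among them for both (highest adjusted p 0.113 and 0.111). mdm-miR167h_1ss22AT, gma-MIR5368-p3_2ss2AT19CA_1 and the candidate PC-3p-68965_76 were listed at 0 in all sensitive controls and at 36.0 ± 13.6, 29.7 ± 8.46 and 35.1 ± 6.24 CPM under HNT, although the first was not called without sensitive control 2 or 3 or sensitive HNT 1 (highest adjusted p 0.059). Of these, osa-miR398a, csi-miR160c-5p_R-1 and osa-miR444d.3_R-1 were each listed at 0 in 1 sensitive control, which makes the size of their rise uncertain. Falls were led by osa-miR1861h_1ss15GA (chromosome 8, 15132727 to 15132836; 407 ± 18.3 to 76.6 ± 8.08 CPM, -2.40 ± 0.17), osa-miR169r-5p_R+1 (-2.41 ± 0.30), bdi-MIR529-p5_1ss7GA (-2.44 ± 0.61, listed at 0 in 1 sensitive HNT library) and osa-MIR11343-p3_1ss23TC (-2.16 ± 0.42). osa-miR1320-5p_L-1R+1, osa-miR529a_L+1, osa-miR166j-5p and zma-MIR164h-p5_2ss4CG17CG were listed at 0 in all sensitive HNT libraries and at 38.9 ± 7.47, 31.6 ± 4.60, 30.8 ± 10.8 and 12.4 ± 1.24 CPM in the controls. The last of these was not called without any 1 sensitive library or tolerant HNT 2 (highest adjusted p 0.086). Among candidates, PC-3p-15463_499 rose by 1.03 ± 0.27, though not without sensitive control 3 or sensitive HNT 2 (highest adjusted p 0.056), and PC-3p-13338_584 by 0.64 ± 0.21, a call that most other settings ended (highest adjusted p 0.307). PC-3p-4597_1608 fell by 1.13 ± 0.22, and PC-3p-18269_415 by 1.26 ± 0.36 except without sensitive control 1 or 3 or sensitive HNT 1 or 3 (highest adjusted p 0.112).

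With scaling by the total count alone, which shifted the median log2 change of all sequences by -0.16 in the sensitive line, the split of calls was 38 higher and 69 lower in place of 50 and 48. Of the 98 calls 86 stayed. Leaving out 1 library moved the number of called families from 31 to 20 without sensitive control 3, 19 without sensitive HNT 3 and 54 without tolerant control 3, a library that correlated less with its group than the rest.

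**Figure D1:**
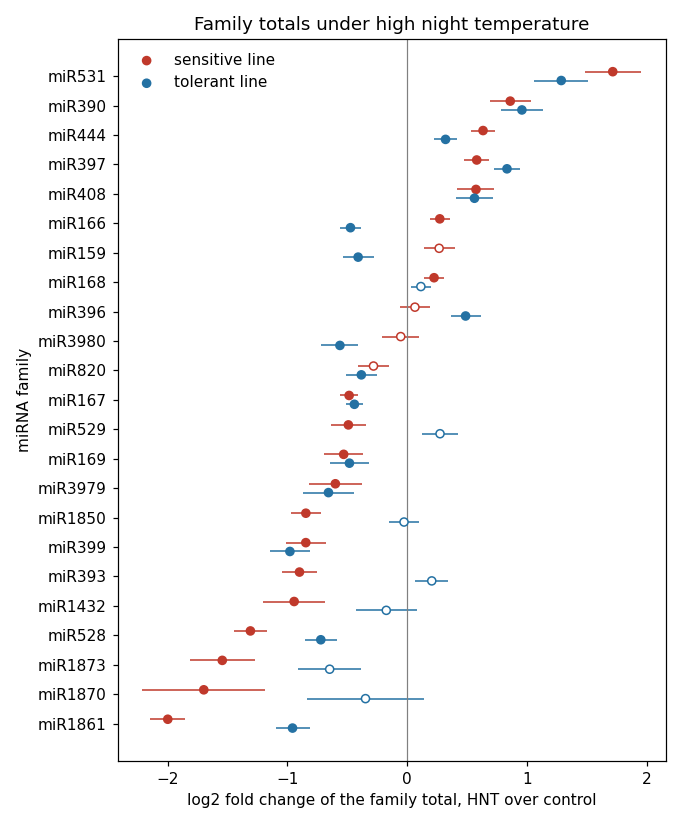
Log2 change under HNT of each called list family in the sensitive and in the tolerant line, with bars for the SE and filled points for an adjusted p under 0.05 over the list families. miR1861 lies at -2.0 in the sensitive and -0.96 in the tolerant line, and miR166 lies at 0.27 and -0.47.

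The same comparison was made in the heat-tolerant line. miR399 fell from 999 ± 213 to 506 ± 28.6 CPM (-0.98 ± 0.17, n = 3 per group, adjusted p = 0.00079) and miR1861 from 419 ± 14.2 to 215 ± 19.8 CPM (-0.96 ± 0.14, adjusted p = 0.00042). miR528 fell from 3695 ± 413 to 2240 ± 138 CPM (-0.72 ± 0.14, adjusted p = 0.00096). The most abundant family, miR166, fell from 412638 ± 33524 to 297064 ± 16660 CPM (-0.47 ± 0.08, adjusted p = 0.00079). miR531 rose from 357 ± 73.2 to 869 ± 40.7 CPM (1.28 ± 0.23, adjusted p = 0.00079) and miR397 from 5246 ± 365 to 9335 ± 339 CPM (0.83 ± 0.11, adjusted p = 0.00017). miR396, which targets growth-regulating factors, rose from 12029 ± 2176 to 16849 ± 1089 CPM (0.49 ± 0.13, adjusted p = 0.011).

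miR390 rose by 0.96 ± 0.17 and miR408 by 0.56 ± 0.15 in the tolerant line, and miR167 fell (-0.44 ± 0.07). miR1425 stood at 0.15 ± 0.08 and did not pass (adjusted p = 0.18). Of 160 families 11 rose and 8 fell; among the list families 6 rose and 10 fell when adjusted over the list alone, against 5 and 6 over all families. Single libraries ended the calls of miR444 (0.32 ± 0.10; without tolerant control 1 or tolerant HNT 2 or 3, highest adjusted p 0.063), miR159 (-0.41 ± 0.13; without tolerant HNT 1 or 2, 0.062) and miR3980 (-0.56 ± 0.15; without tolerant HNT 2, 0.061). They also ended those of miR3979 (-0.66 ± 0.21; without tolerant control 1 or tolerant HNT 2 or 3, 0.10), miR169 (-0.48 ± 0.16; without sensitive HNT 3 or tolerant HNT 1 or 2, 0.12) and miR820 (-0.38 ± 0.13; without sensitive HNT 3, tolerant control 1 or 2 or tolerant HNT 2 or 3, 0.10).

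By sequence 46 rose and 35 fell in the tolerant line, and 142 had an unadjusted p under 0.05. Of the 11 copper and redox sequences 5 rose, 1 fell and 5 did not pass (6 and 1 adjusted over the list alone). aof-miR408_R+1 rose by 1.85 ± 0.34, osa-MIR397b-p3 by 0.94 ± 0.11 and osa-miR398a by 2.41 ± 0.49, and osa-miR528-5p fell (-0.73 ± 0.13). The list passed camera upwards with adjusted p = 0.0418 (limma), and did not with adjusted p = 0.708 with an estimated correlation. Nor did it pass without any 1 of 10 libraries (highest adjusted p 0.236). Of the 24 grain size or filling sequences 7 rose, 1 fell and 16 did not pass (11 and 3 adjusted over the list alone), with osa-miR396a-5p at 0.79 ± 0.14 and osa-miR396c-5p at 0.71 ± 0.12. The rises of the grain list include osa-MIR397b-p3, osa-MIR397b-p5, osa-miR408-3p and aof-miR408_R+1, which the copper and redox list holds too. The results of these lists are thus not separate. For the grain list camera gave adjusted p = 0.02 upwards, and adjusted p = 0.708 with an estimated correlation. The call held without each library (highest adjusted p 0.0434). Yet 6 of 10 ways to split the tolerant libraries 3 against 3, the real one included, gave at least as many list calls. The 7 nutrient sequences included 2 falls, osa-miR399d (-0.95 ± 0.15) and osa-MIR399d-p5 (-1.72 ± 0.44), no rise and 5 that did not pass, the same calls adjusted over the list alone. Camera gave this list adjusted p = 0.0418 downwards, and adjusted p = 0.708 with an estimated correlation. It was not called without tolerant control 3 (0.171) or tolerant HNT 2 (0.0664).

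Of the 24 auxin-signalling sequences 3 rose, 2 fell and 19 did not pass (3 and 2 adjusted over the list alone; camera adjusted p = 0.343), with osa-miR390-3p at 1.18 ± 0.28 and osa-miR167h-3p at -0.80 ± 0.18. Of the 94 developmental sequences 12 rose, 12 fell and 70 did not pass (14 and 14 adjusted over the list alone; camera adjusted p = 0.811). Of the 79 monocot or rice sequences 9 rose, 11 fell and 59 did not pass (9 and 12 adjusted over the list alone; 0.566). Among the 6 sequences from families that target DCL1 or AGO1, the AGO1-targeting arm osa-miR168a-5p fell (-0.33 ± 0.10), its opposite arm osa-miR168a-3p_L-3 rose by 0.56 ± 0.10 and 4 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.811). The 16 heat-response sequences gave 2 rises, 1 fall and 13 not passed (4 and 2 adjusted over the list alone; 0.493), with a median of 0.24 and a mean of -0.04. Of the 5 miR2118 sequences 0 passed over all sequences in edgeR, although 2 had an unadjusted p under 0.05 and DESeq2 called 1, as did limma with the smaller pseudocount. Adjusted over the list alone 1 fell. Camera gave adjusted p = 0.319, while fry called the list downwards (adjusted p = 0.0445, median log2 change -1.18).

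The largest rises in the tolerant line included sequences that resemble the 5' part of transfer RNAs. Of these, ptc-miR6478_R+3_1ss21GA went from 18.8 ± 3.30 to 204 ± 7.82 CPM (3.44 ± 0.19, adjusted p = 8.9e-08), and gma-MIR6300-p3_1ss13AG and gma-MIR6300-p5_1ss8AG rose by 2.61 ± 0.29 and 2.34 ± 0.20. All sequences of that kind together took 0.23% ± 0.06 of table reads in the tolerant controls and 0.786% ± 0.014 under HNT. In the sensitive line they took 0.54% ± 0.05 and 0.607% ± 0.030, so the tolerant controls were the low group, at 0.426 of the sensitive ones. osa-miR398a rose by 2.41 ± 0.49 in edgeR but did not pass in limma on the authors' normalised values (highest adjusted p 0.352), and osa-miR531a_R-2 rose by 2.14 ± 0.22. cas-MIR5139-p3_2ss9AG18GC rose by 2.63 ± 0.64 (listed at 0 in 1 tolerant control), lost with the smaller pseudocount in limma (0.101) and not compared with plastid or 25S ribosomal RNA here, and osa-miR444d.3_R-1 by 2.51 ± 0.71, lost without tolerant control 1 or 2 or any 1 tolerant HNT library (highest adjusted p 0.315 over all settings). bra-MIR5724-p5_2ss2TA18AC and PC-3p-68965_76 were listed at 0 in all tolerant controls and at 35.9 ± 7.55 and 19.6 ± 2.05 CPM under HNT, and PC-3p-13338_584 stood at 0.65 ± 0.20, a call that 7 of 15 other settings ended (0.379). Falls included osa-MIR169a-p3 (-1.67 ± 0.17), osa-miR1850.1 (-1.31 ± 0.19), osa-MIR1879-p5 (-1.23 ± 0.26), osa-miR1861h_1ss15GA (-1.18 ± 0.16), osa-MIR159f-p5 (-1.34 ± 0.27) and PC-3p-9970_789 (-0.74 ± 0.16). osa-MIR399d-p5 (-1.72 ± 0.44) was not called without tolerant HNT 2 or 3 (highest adjusted p 0.065). ath-miR8175_L+3_1ss5AT fell (-1.56 ± 0.36), but stood at 0.29 (adjusted p = 0.612) once its variants were summed. osa-miR1320-5p_L-1R+1, PC-3p-80128_61 and PC-5p-87765_52 were listed at 0 under HNT and at 17.6 ± 2.58, 31.0 ± 17 and 16.9 ± 6.18 CPM in the controls. Any 1 tolerant HNT library or tolerant control 1 or 2 left out ended the calls of both candidates (highest adjusted p 0.122 and 0.092).

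The split of 46 and 35 became 69 higher and 28 lower with scaling by the total count alone, which shifted the median by 0.11, and 74 of the 81 calls stayed. Tolerant control 3 stood apart from the other tolerant controls, and without it 131 sequences and 52 families were called in place of 81 and 19.

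The sequences called in both lines were compared next. Of the called sequences 25 rose in both lines, among them osa-miR398a and osa-miR531a_R-2, where 4.88 would be shared by independent lists of that length (Fisher's exact test, p = 1.2e-15). Another 15 fell in both, among them osa-miR1861h_1ss15GA and osa-MIR169a-p3, where 3.57 would be (Fisher's exact test, p = 1.1e-07). A further 4 were called in opposite directions. Fisher's test treats the sequences as independent units, which near-identical members of a family are not. Across the 471 sequences, which are not independent replicates, the log2 changes of the lines had a Pearson r of 0.467 and a Spearman rho of 0.489. The lines share no library.

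The interaction asked which small RNAs responded differently in the lines; its value is the log2 response of the tolerant line less that of the sensitive line. miR166 rose in the sensitive and fell in the tolerant line, an interaction of -0.75 ± 0.12 (adjusted p = 0.0018, 3 libraries per group). With scaling by the total count alone this was -0.48 ± 0.07, and the rise in the sensitive line was small (0.12 ± 0.05). miR393 had fallen in the sensitive line and stood at 0.20 ± 0.14 in the tolerant line (adjusted p = 0.29), an interaction of 1.10 ± 0.20 (adjusted p = 0.0027). That family total includes osa-miR393b-3p, named for the 3p arm. miR1861 fell in both lines, and by less in the tolerant one (1.04 ± 0.20, adjusted p = 0.0031). The family total of miR1850 had fallen in the sensitive line and stood at -0.03 ± 0.12 in the tolerant line (interaction 0.82 ± 0.18, adjusted p = 0.0059). Its sequences differed: osa-miR1850.1 fell in both lines (-1.27 in the sensitive and -1.31 in the tolerant line). osa-MIR1850-p3, from the other arm, stood at -0.64 and 0.22. The interaction of miR159 was -0.68 ± 0.18 (adjusted p = 0.025).

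The SPL regulator miR529 had an interaction of 0.76 ± 0.21 (adjusted p = 0.025), not called without sensitive control 3, sensitive HNT 2, tolerant control 1 or tolerant HNT 2 or 3 (highest adjusted p 0.08). The NAC regulator miR164 had one of -0.52 ± 0.16 (adjusted p = 0.044), not called without tolerant HNT 2 or with scaling by the total count (highest 0.073). miR528 (0.59 ± 0.19, adjusted p = 0.055), miR444 (-0.31 ± 0.14, adjusted p = 0.17), miR167 (0.04 ± 0.10, adjusted p = 0.93) and miR1425 (0.10 ± 0.12, adjusted p = 0.79) did not pass. Of 160 families the interaction was positive in 10 and negative in 4 that passed; of the list families 4 were positive and 3 negative when adjusted over the list alone, against 4 and 2 over all families.

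By sequence 20 interactions were positive and 11 negative, and 84 had an unadjusted p under 0.05. Those of the tRNA-like ptc-miR6478_R+3_1ss21GA (2.52 ± 0.26), gma-MIR6300-p3_1ss13AG (2.15 ± 0.40) and gma-MIR6300-p5_1ss17AG (1.5 ± 0.28) were among the largest. Others were osa-miR5493_R+4 (2.67 ± 0.54), osa-miR1320-3p_L-1R+1 (2.07 ± 0.36), osa-MIR1879-p5 (-2.41 ± 0.37), osa-miR159f_R-1 (-1.07 ± 0.23) and osa-miR166a-3p (-0.78 ± 0.13, adjusted p = 0.00306). gma-MIR5368-p3_1ss2AT (-2.92 ± 0.65, listed at 0 in 1 sensitive control) was lost in limma (highest adjusted p 0.254), osa-miR164e (-0.89 ± 0.21) without tolerant HNT 2 (0.051), and osa-miR3980a-3p (-0.82 ± 0.22) without sensitive HNT 1 or tolerant HNT 2 (0.084). osa-miR171e-5p (-1.62 ± 0.41) was not called without sensitive control 1 or 2, sensitive HNT 2 or 3 or tolerant HNT 2 or 3 (0.079). bra-MIR5724-p5_2ss2TA18AC, osa-miR529a_L+1 and osa-miR166j-5p were each listed at 0 in 1 of the 4 groups, and gma-MIR5368-p5_2ss1TC21TC, called as negative, at 0 in 2 of the 3 sensitive controls. The call of osa-miR166j-5p was kept without only 2 of the 12 libraries (0.184).

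Of the lists 0 passed camera or the directional test of fry in limma for the interaction, and the copper and redox list and the candidates had an unadjusted camera p under 0.05. The mixed test of fry, which asks for changes in either direction, passed for the auxin (adjusted p = 3e-05), developmental (5.12e-07), copper and redox (0.00574), grain (0.0298), monocot (0.00444) and 21-base lists (1.76e-09). Of the auxin-signalling sequences 2 were positive, osa-miR393a (1.47 ± 0.35) and osa-miR393b-3p (0.96 ± 0.18), the same number adjusted over the list alone, and 22 did not pass (camera adjusted p = 0.932). Of the developmental sequences 3 were positive and 5 negative, the same adjusted over the list alone (0.755). Of the monocot or rice sequences 2 were positive and 1 negative (2 and 0 adjusted over the list alone; 0.486). Of the copper and redox sequences 0 passed over all sequences in edgeR, although 3 had an unadjusted p under 0.05 and DESeq2 called 2 (limma 0), and 2 were positive adjusted over the list alone (0.134). osa-miR2118e was negative (-0.76 ± 0.20), also adjusted over the list alone (camera 0.404). In edgeR 0 sequences of the nutrient (camera 0.784), DCL1 and AGO1 (0.811), heat (0.566) and grain lists (0.226) passed, over all sequences or adjusted over the list alone. Unadjusted p was under 0.05 for 0, 0, 1 and 3 of them, DESeq2 called 3 of the grain list and 0 of the others, and limma called 0. Median and mean differed in sign for the auxin (0.03 and -0.19), developmental (-0.07 and 0.08), 24-base (0.02 and -0.13) and 21-base sequences (-0.02 and 0.01). Without the sequences that resemble pieces of transfer or 18S ribosomal RNA 18 interactions passed in place of 31, and without tolerant control 3, 64 passed. With scaling by the total count alone, which shifted the median by 0.26, 38 were positive and 7 negative. Families with an interaction numbered 7 without sensitive control 3, 8 without sensitive HNT 2 and 8 without tolerant HNT 2, in place of 14.

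**Figure D2:**
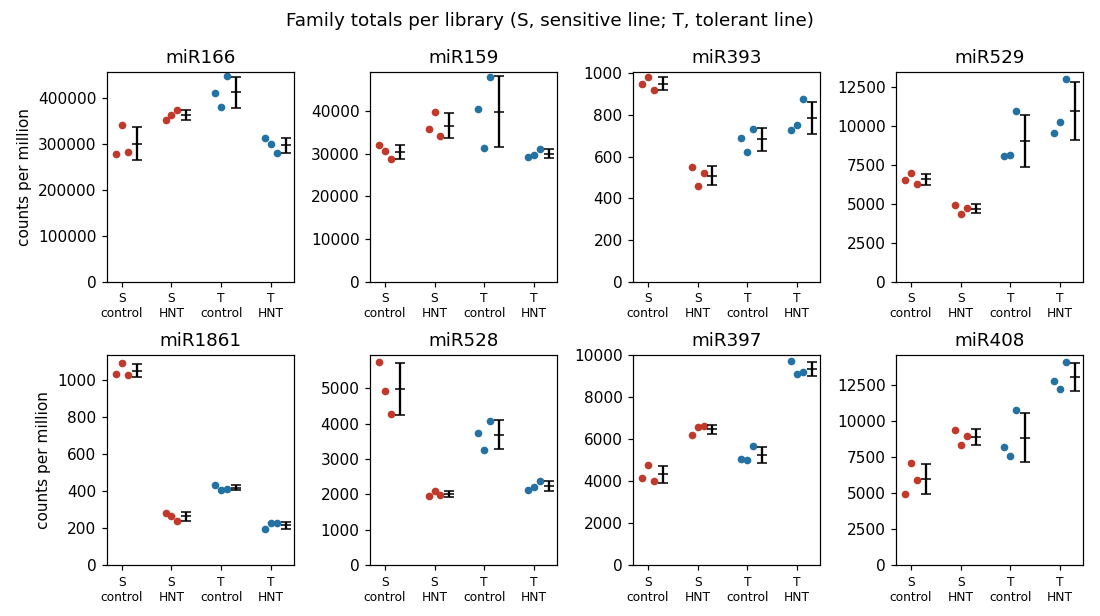
CPM of 8 families in each library (points) with the mean and SD of each group of 3, for the sensitive (S) and tolerant (T) line under control and HNT. The group means of miR393 were 950 and 509 CPM in the sensitive and 683 and 786 CPM in the tolerant line.

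Under control conditions the lines were compared as tolerant less sensitive. miR1861 was lower in the tolerant line (419 ± 14.2 against 1052 ± 34.0 CPM, -1.33 ± 0.14, n = 3 per group, adjusted p = 2.3e-05). miR166 was higher (412638 ± 33524 against 300788 ± 35249 CPM, 0.46 ± 0.08, adjusted p = 0.0033), as was miR164 (36721 ± 5055 against 26196 ± 3160 CPM, 0.49 ± 0.11, adjusted p = 0.014). miR167 (-0.05 ± 0.07, adjusted p = 0.64), miR444 (0.19 ± 0.10, adjusted p = 0.20) and miR1425 (-0.05 ± 0.08, adjusted p = 0.65) did not pass.

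Of 160 families 6 were higher and 5 lower in the tolerant line; of the list families 7 were higher and 4 lower adjusted over the list alone, against 3 and 1 over all families. The other 8 calls over the list families were lost without 1 or more libraries, sensitive control 1 and 3 among them in each case. Those higher in the tolerant line were miR408 (0.56 ± 0.15, highest adjusted p 0.078), miR160 (0.50 ± 0.16, 0.129), miR3980 (0.48 ± 0.15, 0.113), miR529 (0.46 ± 0.15, 0.131) and miR159 (0.39 ± 0.13, 0.151). Those lower were miR528 (-0.43 ± 0.13, 0.131), miR393 (-0.48 ± 0.14, 0.115) and miR1873 (-0.86 ± 0.26, 0.115). Sensitive control 2 ended the same calls except that of miR408. Of these, miR159, miR160, miR529 and miR3980 were also lost with scaling by the total count or by DESeq2's size factors.

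By sequence 20 were higher and 21 lower in the tolerant controls, and 101 had an unadjusted p under 0.05. osa-MIR1430-p5 (chromosome 12, 6825011 to 6825152) was higher (266 ± 33.9 against 105 ± 7.78 CPM, 1.35 ± 0.26), as was stu-MIR8005c-p3_1ss12AG (1.36 ± 0.28). osa-MIR1428g-p5_1ss2GA was listed at 0 in all sensitive controls and at 65.6 ± 6.15 CPM in the tolerant ones. gma-MIR5368-p3_2ss2AT19CA_1 was also listed at 0 in the sensitive controls, against 10.9 ± 7.56 CPM, and not called without sensitive control 3 (highest adjusted p 0.051). osa-miR164e (0.65 ± 0.15) and osa-miR5493_R+4 (-2.04 ± 0.38) passed except when only these groups were fitted (0.083 and 0.052). osa-MIR1879-p5 (1.11 ± 0.26) was lost without sensitive control 3 (0.109) and osa-miR1320-3p_L-1R+1 (-1.11 ± 0.25) without sensitive control 3 or tolerant control 1 (0.085). The calls of osa-MIR1858a-p3 (1.19 ± 0.31), gma-MIR5368-p5_2ss1TC21TC (higher, listed at 0 in 2 of the 3 sensitive controls) and PC-3p-4597_1608 (-0.81 ± 0.21) were kept without only 4, 3 and 2 of the 12 libraries (0.164, 0.129 and 0.164). osa-miR1861e was lower (-1.49 ± 0.17) and bra-MIR5724-p5_2ss2TA18AC was listed at 0 in the tolerant controls. aof-MIR166b-p5_2ss6GC17TG, which holds a conserved stretch of 18S ribosomal RNA, stood at 96.0 ± 100 CPM in the tolerant and 1053 ± 281 CPM in the sensitive controls (-3.50 ± 0.53). The tRNA-like ptc-miR6478_R+3_1ss21GA was lower as well (-2.40 ± 0.20), and gma-MIR6300-p3_1ss13AG (-1.99 ± 0.30) and gma-MIR6300-p5_1ss17AG (-1.58 ± 0.20) were lower unless their variants were summed (highest adjusted p 0.55 and 0.082).

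Among the lists, the 94 developmental sequences had 6 higher, 2 lower and 86 not passed (6 and 2 adjusted over the list alone; camera adjusted p = 0.0798, under 0.05 without any 1 of 9 libraries and 0.796 without tolerant control 3). The lower ones include the 18S-like aof-MIR166b-p5_2ss6GC17TG. The 11 copper and redox sequences had 2 higher, osa-miR408-3p (0.58 ± 0.15) and osa-MIR397b-p3 (0.47 ± 0.11), and 1 lower, osa-miR528-5p (-0.44 ± 0.13), the same adjusted over the list alone (camera adjusted p = 0.702). The grain list had 2 higher and 1 lower (2 and 1 adjusted over the list alone; 0.811) and the monocot or rice list 3 higher and 4 lower (3 and 4 adjusted over the list alone; 0.0617). The last was called downwards by camera with the replicate block (adjusted p = 0.043) and by fry (0.0354), but not with an estimated correlation (0.708). In edgeR 0 sequences of the auxin (camera 0.954), nutrient (0.404), DCL1 and AGO1 (0.964), heat (0.555) and miR2118 lists (0.954) passed, over all sequences or adjusted over the list alone. Unadjusted p was under 0.05 for 6, 0, 0, 4 and 0 of them, DESeq2 called 2 of the auxin and 1 of the heat sequences and 0 of the others, and limma called 0. Camera was upwards with a median of -0.08 and a mean of 0.26 for the auxin list and a median near 0 and a mean of 0.08 for the candidates. It was downwards with 0.09 and 0.16 for the DCL1 and AGO1 list. The split of 20 and 21 became 11 higher and 34 lower with scaling by the total count alone, which shifted the median by -0.20. Without the sequences that resemble transfer or 18S ribosomal RNA 24 passed in place of 41, with only these groups in the fit 15, without sensitive control 3, 27, and without tolerant control 3, 52. The number of families was 18, 19 and 19 without tolerant control 1, 2 and 3 in place of 11.

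Under HNT, miR529 was higher in the tolerant line (10952 ± 1858 against 4691 ± 278 CPM, 1.22 ± 0.15, n = 3 per group, adjusted p = 0.00012). miR1850 was higher (1205 ± 16.1 against 723 ± 64.5 CPM, 0.74 ± 0.12, adjusted p = 0.0016), as were miR397 (9335 ± 339 against 6471 ± 214 CPM, 0.53 ± 0.10, adjusted p = 0.0041) and miR393 (0.63 ± 0.14, adjusted p = 0.0093). The last was not called without sensitive HNT 2 or tolerant HNT 3 (highest adjusted p 0.06). miR167 (-0.01 ± 0.07, adjusted p = 0.96), miR444 (-0.13 ± 0.10, adjusted p = 0.44), miR159 (-0.29 ± 0.13, adjusted p = 0.18) and miR1425 (0.05 ± 0.08, adjusted p = 0.75) did not pass.

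Of 160 families 8 were higher and 1 lower; among list families 7 were higher and 2 lower adjusted over the list alone, against 4 and 0 over all families. The calls of miR408 (0.55 ± 0.15, highest adjusted p 0.091), miR169 (0.51 ± 0.16, 0.192), miR396 (0.39 ± 0.12, 0.154), miR166 (-0.29 ± 0.08, 0.078) and miR2118 (-0.65 ± 0.19, 0.139) were each lost without any 1 of sensitive HNT 2 and 3 and tolerant HNT 1, 2 and 3. Those of miR169, miR396 and miR2118 were lost without sensitive HNT 1 or sensitive control 3 as well, and those of miR169 and miR2118 without tolerant control 1. By sequence 15 were higher and 2 lower, and 80 had an unadjusted p under 0.05. osa-MIR529a-p5 (chromosome 2, 16227805 to 16227903) stood at 10868 ± 1833 against 4673 ± 271 CPM (1.22 ± 0.14), osa-MIR1430-p5 at 190 ± 40.3 against 41.7 ± 19.5 CPM (2.15 ± 0.29) and osa-MIR1850-p3 at 1.05 ± 0.14. osa-miR529a_L+1 and osa-miR166j-5p were listed at 0 in all sensitive HNT libraries and at 26.6 ± 4.10 and 10.9 ± 1.08 CPM in the tolerant ones, and the second was not called without any 1 sensitive HNT library or tolerant HNT 1 or 3 (0.062). osa-miR169r-5p_R+1 (1.60 ± 0.31) was lost without sensitive HNT 1 (0.066), osa-MIR6250-p5 (1.75 ± 0.40) without any 1 of the HNT libraries (0.179), and osa-miR169r-3p (1.23 ± 0.31) was kept without only 3 of the 12 libraries (0.174). osa-miR2118e was lower (-0.86 ± 0.14), as was osa-MIR1879-p5 (-1.31 ± 0.26), the latter not without sensitive HNT 1 or 2 or tolerant HNT 1 or 3 (0.098).

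The copper and redox list passed camera upwards under HNT (adjusted p = 0.00517), with osa-miR398b (0.99 ± 0.21), osa-MIR397b-p5 (0.65 ± 0.13) and osa-MIR397b-p3 (0.48 ± 0.11) higher, none lower and 8 not passed (5 and 0 adjusted over the list alone). It gave adjusted p = 0.708 with an estimated correlation, and held without each library (highest adjusted p 0.0381). Yet 4 of 10 ways to split the HNT libraries 3 against 3, the real one included, gave at least as many list calls. Of the developmental sequences 6 were higher and 88 did not pass (9 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.404). The auxin list had 1 higher, osa-miR393b-3p (0.54 ± 0.13; 2 and 1 adjusted over the list alone; 0.702), and the grain list 2 higher (4 and 1 adjusted over the list alone; 0.111). The heat list had 1 higher, osa-miR398b (1 and 1 adjusted over the list alone; 0.932), and the monocot or rice list 1 higher, osa-MIR1850-p3 (1 and 0 adjusted over the list alone; 0.418). The miR2118 list had 1 lower, osa-miR2118e (0 and 1 adjusted over the list alone; 0.279). In edgeR 0 nutrient sequences passed, over all sequences or adjusted over the list alone (camera 0.702), nor did any by DESeq2, limma or unadjusted p under 0.05. Of the DCL1 and AGO1 sequences 0 passed over all in edgeR and limma, 1 had an unadjusted p under 0.05, DESeq2 called 1 and 1 was lower adjusted over the list alone (0.809). Their median was 0.03 and their mean -0.20. The count of 17 depended on the settings: it was 40 with DESeq2, 61 with only these groups in the fit, 9, 10 and 11 without sensitive HNT 1, 2 and 3, 11 without tolerant HNT 1 or 3, and 50 without tolerant control 3. The 9 called families became 5 without sensitive HNT 2 or 3 or tolerant HNT 2 or 3, and 26 without tolerant control 3.

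The share of table reads by length was compared last, as a description of the makeup of the libraries. In the sensitive line the 24-base class went from 8.45% ± 0.50 to 6.12% ± 0.09 under HNT and the 22-base class from 8.67% ± 0.42 to 5.92% ± 0.12 (SD, n = 3). The 21-base class went from 79.0% ± 0.92 to 84.2% ± 0.25 (SD, n = 3; exact permutation p = 0.1 for each, two-sided, the smallest that 3 against 3 can give). In the tolerant line the 24-base class stood at 6.17% ± 2.02 in the controls and 5.71% ± 0.72 under HNT (n = 3, exact permutation p = 0.7). This rested on tolerant control 3, which had 3.84% against 7.19% and 7.48% in tolerant controls 1 and 2. Without it the controls stood at 7.33% ± 0.20 and the change was -1.63 points, with no overlap. Without tolerant control 1 or 2 the change was 0.05 or 0.19 points. Of the 20 comparisons of a length class between groups 13 had no overlap between the libraries, and the smallest Benjamini-Hochberg adjusted value was 0.154. Without tolerant control 3, 17 had no overlap. Chance gives 10% for a single comparison of 3 with 3. The comparisons are not independent, since the shares of a library depend on each other and each group recurs in several contrasts. Among single 24-base sequences 3 rose and 14 fell in the sensitive line and 130 did not pass (2 and 11 adjusted over the list alone; camera adjusted p = 0.246), and in the tolerant line 3 rose and 5 fell (3 and 0; 0.337). Without tolerant control 3 camera called the 24-base list downwards in the tolerant line (adjusted p = 2.85e-05), but not with an estimated correlation (0.556). Between lines the 24-base list was lower in the tolerant controls (camera adjusted p = 0.00517; 1 higher and 4 lower; 0 and 1 adjusted over the list alone). The 21-base list was higher there (0.0418; 13 higher and 5 lower; 13 and 5 adjusted over the list alone). Both had adjusted p = 0.819 with an estimated correlation, and fry called neither (0.525 and 0.441). Both calls rested on tolerant control 3: without it the 24-base list was upwards (camera adjusted p = 0.796) and the 21-base list stood at 0.651. They were also lost without sensitive control 3 (0.0523 and 0.124). Under HNT the 24-base list was lower in the tolerant line (camera adjusted p = 0.00817, and adjusted p = 0.819 with an estimated correlation), but not without tolerant HNT 3 (0.162) or by fry (0.74). Of its 147 sequences 0 passed in edgeR, over all sequences or adjusted over the list alone, 11 had an unadjusted p under 0.05, DESeq2 called 1 and limma 0.

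Among 21-base sequences 26 rose and 21 fell in the sensitive line (27 and 23 adjusted over the list alone; camera adjusted p = 0.954) and 18 rose and 20 fell in the tolerant line (19 and 20; 0.653). For the interaction 9 were positive and 7 negative (9 and 9; 0.529), and between lines under HNT 10 were higher and 1 lower (13 and 6; 0.329). The 24-base list had 1 positive interaction (1 and 0; 0.915), and camera called it downwards without tolerant control 3 (0.0412), though not with an estimated correlation (0.657). Of the 77 authors' candidates tested, 3 rose and 2 fell in the sensitive line (1 and 1 adjusted over the list alone; 0.811), 2 rose and 3 fell in the tolerant line (1 and 1; 0.493), and 1 was lower in the tolerant controls (0 and 0; 0.854). In edgeR 0 candidates passed for the interaction (0.143), with 4 at an unadjusted p under 0.05 and 0 by DESeq2 and limma, and 0 between lines under HNT (0.111), with 9 unadjusted, 1 by DESeq2 and 0 by limma.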

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

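The tests of tRNA-like sequences, of a length shift in tolerant control 3 and of single abundant sequences were chosen only after the results were seen.

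The results of this paragraph and the transfer RNA-like sequences below were singled out because the responses of the lines differed in the interaction test. Family totals with a difference above 0, tolerant less sensitive, were miR393 (1.10), miR1861 (1.04), miR1850 (0.82) and miR529 (0.76), and those below 0 were miR166 (-0.75), miR159 (-0.68) and miR164 (-0.52). Among single sequences the difference was 2.67 for osa-miR5493_R+4, 2.07 for osa-miR1320-3p_L-1R+1, -2.92 for gma-MIR5368-p3_1ss2AT and -2.41 for osa-MIR1879-p5. It was -1.62 for osa-miR171e-5p, -1.07 for osa-miR159f_R-1, -0.89 for osa-miR164e, -0.82 for osa-miR3980a-3p and -0.78 for osa-miR166a-3p. The fitted values 7.19 for bra-MIR5724-p5_2ss2TA18AC, 6.17 for osa-miR529a_L+1 and 5.26 for osa-miR166j-5p involve a group listed at 0 and are not bounds. Nor is -5.63 for gma-MIR5368-p5_2ss1TC21TC, listed at 0 in 2 of the 3 sensitive controls.

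Of 100 splits of the libraries of both lines, 2 gave as many interactions as the real split, 31 sequences and 14 families. The splits were drawn at random and include the real one. That share is under 0.05, but most splits mix control and HNT libraries, which puts the HNT responses into the spread between libraries. Low counts were thus built in, and these splits cannot exclude chance for a difference between the lines. The highest other split gave 154 sequences and 34 families. That split exchanges control and HNT in the tolerant line, and so measures the sum of both responses, a structure of the samples. Without it the highest was 17 sequences and 6 families. Overlap of the responses of both lines, 40 sequences, was reached by 1 of 100 splits, the real one, with 4 as the highest other. Libraries regrouped within a line gave 0 calls, so these splits do not test the overlap.

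For comparisons of 3 libraries with 3 there are only 10 splits, too few for a share under 0.05. For the sensitive response 1 split, the real one, reached 98 sequences and 1 reached 31 families, with 0 and 0 as the highest others. For the tolerant response 1 reached 81 sequences and 1 reached 19 families, with 0 and 0. Between controls 1 reached 41 sequences and 1 reached 11 families, with 0 and 1, and under HNT 1 reached 17 sequences and 1 reached 9 families, with 1 and 0. For the lists that passed camera, 6 splits reached the 3 of the tolerant response (highest other 5), 9 the 2 between controls (highest other 4) and 4 the 2 under HNT (highest other 2). The real split is included in each count. Other groupings of the same libraries thus often gave as many list calls. The list calls of camera at the preset correlation therefore cannot be told apart from those of arbitrary groupings.

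Sequences like the 5' part of transfer RNAs rose under HNT in the tolerant line: the interaction was 2.52 for ptc-miR6478_R+3_1ss21GA, 2.15 for gma-MIR6300-p3_1ss13AG and 1.5 for gma-MIR6300-p5_1ss17AG. They took 0.23% of reads in the tolerant controls, 0.786% in tolerant HNT, and 0.54% and 0.607% in the sensitive groups, so low tolerant controls are part of the pattern. The ratio of 5' to 3' pieces was 2.75 times higher under HNT than in the controls of that line (1.94 against 0.705, with 2.50 and 1.90 in the sensitive groups). The 3' pieces held 0.2%, 0.282% and 0.648% in tolerant controls 1 to 3 and 0.376% to 0.43% under HNT, so without tolerant control 3 they rose as well. General breakdown of RNA thus cannot be told apart from a change of the 5' pieces alone. Scaling is argued against, since the lowest interaction of the miR6300 family over the scalings was 1.15. The authors' removal of transfer RNA reads, which left 22 such sequences in the table, cannot be told apart from a change in the plants, because the removed reads are not analysed here. A response of the tolerant line to HNT stays open as well.

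Tolerant control 3 lay apart from the other tolerant controls (chi-square over degrees of freedom 40.3 and 43.5, against 5.28 for that pair of controls). An HNT library under a control label is argued against by its score of 0.235 between the other tolerant controls (0) and tolerant HNT (1), over 98 sequences. A sensitive-line library is argued against by its score of 1.81 between the sensitive (0) and the other tolerant controls (1), over 17 sequences called between the lines under HNT. On this score the sensitive HNT libraries stood at -4.42, -5.03 and -4.49. The tolerant HNT libraries stood at 1.64, 1.78 and 2.50, a range that holds tolerant control 3. A shift in the lengths captured is a candidate explanation: its 24-base sequences lay -1.29 (log2) from its 21-base ones, against -0.34 to 0.77 in the other 11 libraries, and its 18- to 20-base ones 1.13. The upper end, 0.77, is that of tolerant control 2, set against a mean that includes tolerant control 3. These values restate the low 24-base share of tolerant control 3 and so do not test that explanation. A difference between plants was not tested.

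The 22- and 24-base shares of table reads were lower in each sensitive HNT library than in each sensitive control. At 22 bases osa-miR167d-5p_R+1 accounted for 102% of the fall, so that 1 sequence may carry it. At 24 bases osa-miR1874-3p accounted for 57.4%, and without it the share still differed by -0.996 points with no overlap, which argues against that sequence as the whole cause. Dilution by 21-base sequences as the whole cause is argued against by the log2 ratio of -0.31 in 24-base counts per TMM-scaled library size. That ratio includes osa-miR1874-3p. Whether dilution and that sequence together account for the fall was not tested. An effect of HNT on the 24-base class in this line remains a hypothesis, as the smallest exact p the design allows is 0.1.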

How the results depend on the processing

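The runs without sequences like transfer or 18S ribosomal RNA, with 1 entry kept per sequence, with the authors' factors and with a mean of at least 50 reads, and camera without each library, were tests chosen only after seeing the data. Of 85 results of 55 named sequences 47, and of 62 calls of list families 35, kept direction and call under every alternative and every left-out library run; 1 reversed, ath-miR8175_L+3_1ss5AT in the tolerant line, at 0.29 when variants were summed. The interaction count was 48 with DESeq2 and 18 without the RNA-like sequences (main 31). The control line difference was 15 with only its groups in the fit, 24 summed per name and 24 without the RNA-like sequences (main 41). The HNT line difference was 31 with no scaling, 35 with no filter, 40 with DESeq2, 26 with limma on log2 of the normalised value plus 1, 61 with only its groups, 31 with family names only and 28 with 1 entry kept (main 17). Families differing between controls were 6 with rice names only (main 11), between lines under HNT 16 with no scaling (main 9), and 0 lists held with an estimated correlation (main 7). By construction the runs without RNA-like sequences or with only the compared groups hold fewer sequences or libraries; otherwise the cause was not tested.

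Leaving out each library gave 77 to 134 sequences for the sensitive response, 61 to 131 for the tolerant response, 22 to 64 for the interaction, 27 to 52 between controls and 9 to 50 between lines under HNT; each highest value was without tolerant control 3. Families ran from 19 to 54, 13 to 52, 7 to 21, 8 to 19 and 5 to 26 in that order, and length classes without overlap from 13 to 17. Lists called by camera ran from 5 to 8, and camera's adjusted p for the 24-base list between controls from 8.07e-07 to 0.796. That list reversed without tolerant control 3 (upwards, 0.796). For the interaction, fitting only the groups compared is the main fitting itself.

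Replicate numbers gave no clear pairing of the libraries: correlations of deviations between same-numbered libraries ran from -0.135 to 0.138, 3 of 18 exceeded 0.1, and 5 of 12 libraries correlated best with their own number. Between control and HNT they were 0.084, 0.138 and 0.104 in the tolerant line and -0.096, 0.101 and 0.046 in the sensitive line. A weak pairing within the tolerant line is thus not excluded. With the replicate block the counts were 91, 77, 27, 35 and 13 sequences and 28, 16, 13, 10 and 8 families, and 8 lists, none beyond 1.5 times. The table's floor of 5 copies limits sequences near it: groups listed at 0 have no fold.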

Other observations

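The families described here were chosen, as were their tests, only after the results were seen, while the tests of the arms of a hairpin were set beforehand.

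Families outside the fixed lists changed as well. In the tolerant line miR530, which represses grain size through a PLUS3-domain factor in rice, rose from 22537 ± 3272 to 42226 ± 5944 CPM (0.91 ± 0.14, n = 3 per group, edgeR adjusted p = 0.00092) and stood at 0.12 ± 0.14 in the sensitive line (adjusted p = 0.64), an interaction of 0.79 ± 0.20 (adjusted p = 0.025). miR1866 rose in both lines, by 1.03 ± 0.21 (adjusted p = 0.0037) and 1.27 ± 0.21 (adjusted p = 0.0012), and miR439 fell in both (-0.44 ± 0.14, adjusted p = 0.047, and -0.53 ± 0.14, adjusted p = 0.028). miR1320 fell in the sensitive line from 182 ± 21.3 to 50.6 ± 13.7 CPM (-1.84 ± 0.27, adjusted p = 0.00044) and stood at 0.23 ± 0.26 in the tolerant line (interaction 2.07 ± 0.38, adjusted p = 0.0048). miR1430 was higher in the tolerant line both in the controls (1.35 ± 0.28, adjusted p = 0.0092) and under HNT (2.15 ± 0.30, adjusted p = 0.0008).

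Several other families fell in the sensitive line and did not pass in the tolerant one, a difference that itself did not pass. miR11343 fell from 190 ± 32.1 to 41.9 ± 12.4 CPM (-2.17 ± 0.38; interaction 1.08 ± 0.52, adjusted p = 0.30), miR11339 from 685 ± 98.3 to 275 ± 7.01 CPM (-1.32 ± 0.25; interaction adjusted p = 0.22) and miR1874 from 34164 ± 3338 to 21281 ± 979 CPM (-0.68 ± 0.18; interaction adjusted p = 0.59). miR5368, a family from soybean names, rose in the sensitive line from 21.2 ± 20.8 to 489 ± 55.5 CPM (4.46 ± 0.62, adjusted p = 0.00037). Of its sequences, gma-MIR5368-p3_2ss2AT19CA_1 was listed at 0 in all sensitive controls and gma-MIR5368-p5_2ss1TC21TC in 2 of the 3. The control total thus lies near the floor of 5 copies, and the size of the rise is uncertain. The miR5368 sequences were not compared with plastid or 25S ribosomal RNA here.

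A hypothesis was that the 5p and 3p arms of a hairpin change together under HNT. Of 69 hairpin names with both arms 3 were left out, because the table does not list both arms on 1 hairpin, a filter added after the results were seen. Over the other 66 hairpins, which are not independent replicates, Pearson's r was 0.239 in the sensitive line (permutation p = 0.061, adjusted over the 2 lines 0.122) and Spearman's rho 0.33 (permutation p = 0.00688). Without the 2 hairpins whose 5p arm lay farthest from the median of that arm, r was 0.201. Left in was miR529a, whose 3p arm osa-miR529a_L+1 had a fitted change of -7.08 with all sensitive HNT libraries listed at 0. In the tolerant line r was 0.0743 (permutation p = 0.529, adjusted 0.529) and rho 0.172 (permutation p = 0.169), with r = 0.252 without the 2 farthest. Pearson's r did not pass in either line, so whether arms move together stays open. Both arms were called in 9 hairpins in the sensitive and 6 in the tolerant line, and in 1 of each they went in opposite directions. In the sensitive line this was the hairpin of miR166a, with osa-miR166a-5p at -1.30 and osa-miR166a-3p at 0.30, and in the tolerant line that of miR168a, with osa-miR168a-5p at -0.33 and osa-miR168a-3p_L-3 at 0.56.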
